A study of Mus musculus with 22 samples.

How the data were processed

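The series held 22 two-colour hybridisations of uterine RNA to an Agilent mouse oligonucleotide array. Per the labels, RNA of 3 to 4 uteri was pooled, extracted with Trizol and purified on columns, amplified and labelled with cyanine dyes by a low-input protocol, and equal amounts of both labelled cRNAs were hybridised. Each of 11 comparisons had 1 treated pool and 1 vehicle pool on 2 arrays with exchanged dyes. Whether comparisons shared a vehicle pool, the dose of 19NT and the genotype of the mice given DHT are not given in the sources used here.

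The authors deposited the Agilent Feature Extraction output of each array, version 7.5 for 18 arrays and 8.1 for 4. The deposited mean and background signals are intensity values in scanner units. The deposited LogRatio column is a log10 ratio of red over green, and the deposited table of values is the log10 ratio turned to treated over vehicle, with medians per array between -0.00303 and 0.000215. The deposited p-value column was computed by the software from its own error model of each log ratio, per the file headers. The deposited flags (other: well above background, saturated, outlier) are 0 or 1 per spot. Each array had 22393 spots, of which 1075 were controls, and 20868 distinct probes. Reference symbols were given to 18609 probes and 2259 kept the name in the file.

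Mean signals less local background by normexp with an offset of 50 were normalised by loess within each array in limma 3.58.1 under R 4.3.3. Spots with an outlier flag were left out, spots of a probe were averaged, ratios were turned to treated over vehicle, and the probe with the highest mean intensity stood for each gene. Median signals were 201 to 561 in green and 183 to 516 in red, and saturated spots made up 0.00469% to 0.225%. For arrays, their number limits the precision. A gene was called when both arrays gave a log2 ratio of at least 1 in size and the same sign, no outlier flag stood on either array, and the probe was well above background on both arrays in the treated or in the vehicle RNA. Where the labels and file headers let extraction days be told apart, the WT arrays for E2 and estren shared 1 day, the aERKO arrays for E2 and estren fell on others, and the 19NT arrays of both genotypes shared 1 day.

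The rules of calling, the 19 gene lists, the named genes and the alternatives were chosen before the data were examined. Named genes were the 10 highest and 10 lowest called genes with a symbol in the 4 WT comparisons of E2 and estren and the 5 highest and 5 lowest in the other 7, the 10 largest differences each way past the threshold in the genotype fits, the 4 members with the largest values in each list, the 5 largest differences each way between compounds, and a fixed set that included Esr1, Pgr, Ltf, Igf1, Cdkn1a, Vegfa, Fos, Myc, Mad2l1, Ccnb1, Greb1 and Fkbp5. Some genes that this rule names are not reported here. Genes named as shared between genotypes, and single members of lists beyond these, were chosen after their values were seen. The lists were early response, DNA replication, mitosis, secretory epithelium, ribosome biogenesis, chaperones, cholesterol synthesis, steroid receptors, targets of androgen, progesterone and glucocorticoid receptors, growth factor and Wnt genes, vascular genes, and markers of macrophages, granulocytes and mast cells, T, B and NK cells, smooth muscle, epithelium, stroma, erythrocytes and adipose tissue. The median of a list was set against 10000 random lists of its size drawn within 20 bins of mean intensity, and it stood apart outside their central 95%; 108 medians over the 19 lists and 11 comparisons did. With so many medians, some stand apart by chance.

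The genotype difference was fitted in limma on the 10 dye-swap means of the conditions given to both genotypes, with condition as a block, 3 residual degrees of freedom and a prior of 2.29, two-sided, with Benjamini-Hochberg adjustment. Lists were tested in these fits with fry and with camera, with the preset and with an estimated correlation. Compounds were compared without a test, by medians, correlations and shared calls; intervals of a difference cover array error alone, from a fit of all single arrays with 10 residual degrees of freedom. The covariance between compounds was set beside the mean of 100 simulations of unchanged pools against a shared vehicle pool. The spread of pools in the simulations was taken from the aERKO comparisons. They hold no vehicle difference particular to the WT pools, so an excess over them does not measure what lies beyond shared controls. Signals per channel used for Esr1 and vehicle levels were scaled between arrays by Aquantile.

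The alternatives were the deposited log ratio, the deposited table of values, no background subtraction, median centring, no filter on dim probes or outlier flags, the mean of the 2 arrays alone, the deposited p under 0.001 on both arrays, the mean over probes, each array alone, and in the genotype fit no block and each compound left out. Values were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and drawn with matplotlib 3.10.9. The calling rule, the genotype fit and the list medians were tested on simulated data.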

Results

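Gene expression in the mouse uterus was compared between treated and vehicle-treated mice on 22 two-colour oligonucleotide arrays. The arrays formed 11 comparisons. In each, 1 pool of RNA from treated uteri was hybridised against 1 pool from uteri given sesame oil, on 2 arrays with the dyes exchanged. Wild-type (WT) mice and aERKO mice, in which the estrogen receptor alpha gene Esr1 is disrupted, received estradiol (E2) or the synthetic steroid estren, and uteri were taken 2 h or 24 h later. Both genotypes were also examined 24 h after a compound named 19NT in the labels, which state no dose for it, and 1 further comparison used dihydrotestosterone (DHT) for 24 h in mice whose genotype the labels do not state. Doses were 1 µg of E2, 300 µg of estren and 50 µg of DHT per mouse. The title of the series names the question, whether estren acts in the uterus as an estrogen or as a selective activator of non-genomic signalling.

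The pooled design left no biological replicates within a comparison, so no p-value belongs to any of the 11. Each value below is the mean log2 ratio of treated over vehicle on the 2 arrays, and the ± gives the distance of each array from that mean, which reflects array error and not variation between mice. A gene was counted as higher or lower when both arrays passed 2-fold in the same direction. Between 17522 and 18812 genes were measured per comparison, and 86.9% to 98.0% of probes were well above background in a given RNA on a given array. No gene met the rule by dye alone, that is with red over green past 2-fold on both arrays, in any comparison.

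**Figure D1:**
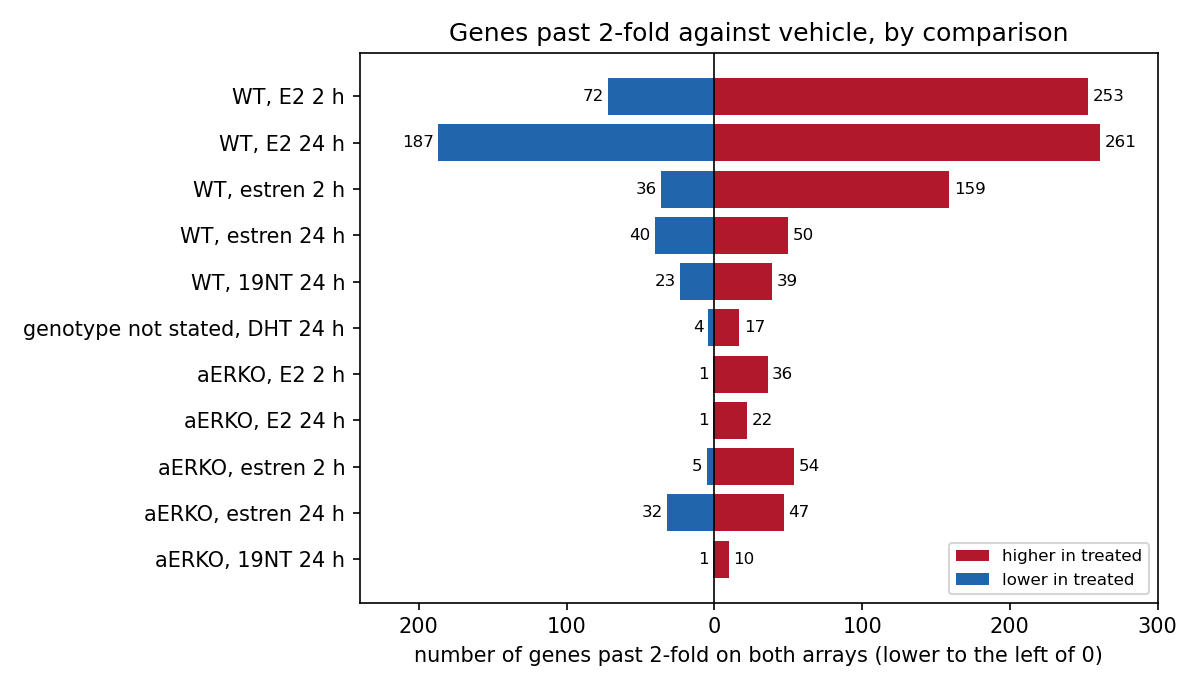
Number of genes past 2-fold against vehicle on both arrays in each of the 11 comparisons, with genes higher in treated uteri to the right of 0 and genes lower to the left. WT uteri after E2 gave 253 higher and 72 lower genes at 2 h and 261 higher and 187 lower at 24 h, against 36 and 1, and 22 and 1, in aERKO uteri.

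Esr1, the targeted gene, was read in both genotypes. Its vehicle signal averaged 7.61 (log2) over the 5 WT comparisons, with a range of 7.32 to 8.21, and 7.30 over the 5 aERKO comparisons, with a range of 7.13 to 7.43. The difference of 0.30 lay within the spread of the WT comparisons, and the highest WT value came from 1 array. Where the probe lies relative to the disrupted part of the gene is not known, so this level says nothing about the genotype labels. Esr1 was not called in any comparison, with ratios such as 0.02 ± 0.05 in WT uteri 2 h after E2.

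E2 at 2 h in WT uteri asked which transcripts estradiol changes early. Inhbb, which encodes the beta B subunit of activins and inhibins, rose most, by 4.65 ± 0.09. Next came Gadd45g (3.99 ± 0.20), a stress-inducible growth-arrest gene, the mitotic checkpoint gene Mad2l1 (3.68 ± 0.14), the transcription factor gene Cebpb (3.68 ± 0.28), the kallikrein genes Klk1b5 (3.52 ± 0.22) and Klk1b8 (3.44 ± 0.09), the pseudogene Klk1b7-ps (3.67 ± 0.09), Rasd1 (3.29 ± 0.05), Errfi1 (3.12 ± 0.06), a feedback inhibitor of EGF receptor signalling, and Greb1 (3.07 ± 0.03), a cofactor of estrogen receptor alpha. The kallikrein family is so alike in sequence that its probes may read one another's transcripts. The largest falls were in Rgs2 (-3.10 ± 0.19), a regulator of G-protein signalling, the potassium channel gene Kcnj8 (-2.84 ± 0.01), Ppp1r14c (-2.68 ± 0.21), Txnip (-2.60 ± 0.07), an inhibitor of thioredoxin, Zfp503 (-2.59 ± 0.59), Lratd1 (-2.56 ± 0.10), Creb3l3 (-2.49 ± 0.80), the Wnt inhibitor gene Apcdd1 (-2.41 ± 0.07) and Trim68 (-2.38 ± 0.69).

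Of the 32 measured early response genes, 17 rose and none fell 2 h after E2 in WT, with Egr1, Junb, Jun and Fos among them; the median was 1.33, against -0.08 to 0.06 for the central 95% of random lists. Fos rose by 1.74 ± 0.02 although its vehicle signal was well above background on 1 of the 2 arrays. Ribosome biogenesis genes had a median of 0.37, and 4 of 24 rose, led by Rrs1 (1.71 ± 0.15) and Gnl3 (1.62 ± 0.23). In the chaperone list 5 of 36 rose, among them Hsph1 (1.62 ± 0.07) and Hspa5 (1.24 ± 0.08), and in the cholesterol list 3 of 21 rose, Idi1 (1.42 ± 0.16) and Fdft1 (1.20 ± 0.18) among them. The steroid receptor and coregulator list stayed centred on 0.00, with 3 members higher, Greb1 and Nrip1 among them, Nr2f2 lower at -1.37 ± 0.26 and 12 of 16 neither. Among growth factor and Wnt genes Inhbb and Wnt4 (2.26 ± 0.04) rose and 29 of 31 did neither, and the median was -0.01. Adm, which encodes the vasodilator adrenomedullin, and Vegfa (1.28 ± 0.01) rose among 24 vascular genes, whose median was 0.00. Targets of androgen, progesterone and glucocorticoid receptors had a median of -0.01, with Sgk1 higher (1.80 ± 0.24) and Hoxa10 (-1.67 ± 0.21) and Tsc22d3 (-1.27 ± 0.10) lower. Pgr (0.87 ± 0.01), Igf1 (1.00 ± 0.22) and Myc (0.67 ± 0.06) were not called, nor was the late gene Ltf (-0.45 ± 0.08), while the cell cycle inhibitor gene Cdkn1a rose by 2.18 ± 0.24.

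Among markers of cell types 2 h after E2 in WT, smooth muscle markers had a median of 0.40, with the oxytocin receptor gene Oxtr called (1.65 ± 0.19), and epithelial markers a median of -0.26 with no member called. The medians of T, B and NK cell markers (-0.03), granulocyte and mast cell markers (0.03), erythrocyte markers (0.04), stromal markers (-0.05) and the adipose and adjacent tissue list (-0.07) lay within the central 95% of random lists. Within that last list the 6 members called lower in WT 24 h after estren, used below as adipose markers, had a median of -0.57. All 6 stood below 0 here and none was called. The count of 325 genes became 548 with the log ratio computed by the scanner software and 505 to 702 on either array alone. Some of the lower genes, Ppp1r14c, Creb3l3 and Trim68 included, belonged to a set of 12 whose median vehicle signal was 11.14 in the WT E2 and estren comparisons and 8.13 in the WT 19NT comparison.

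By 24 h after E2 in WT uteri a different set of genes was at the top. Sprr2f, a small proline-rich protein of cornified epithelia, rose by 3.83 ± 0.04. Enzymes of cholesterol synthesis were also high, among them Idi1 (3.06 ± 0.12) and Fdps (2.84 ± 0.04), with the peptidylarginine deiminase gene Padi2 (3.16 ± 0.54), Clca1 (2.84 ± 0.16), which encodes a secreted protein of mucous epithelia, the alkaline phosphatase gene Alpl (2.82 ± 0.08), the siderophore-binding protein gene Lcn2 (2.63 ± 0.34), the type I collagen gene Col1a1 (2.41 ± 0.22) and Fkbp11 (2.41 ± 0.04), an endoplasmic reticulum prolyl isomerase. Ltf, which encodes the secretory protein lactoferrin, rose by 1.77 ± 0.02 and the growth factor gene Igf1 by 1.52 ± 0.30. Among the lowest were Ppp1r14c (-4.05 ± 0.27), Galnt15 (-3.52 ± 0.02), the matrix protein gene Tgfbi (-3.44 ± 0.22), Creb3l3 (-3.39 ± 0.79), Trim68 (-3.20 ± 0.61), the methyltransferase gene Inmt (-3.09 ± 0.01), Ptprz1 (-3.07 ± 1.19), Trim3 (-2.97 ± 0.38) and Syt6 (-2.95 ± 1.15). Ppp1r14c, Creb3l3, Trim68, Ptprz1 and Trim3 belong to the 12 genes with the high vehicle signal in the WT E2 and estren comparisons.

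In the mitosis list 14 of 30 rose and none fell 24 h after E2 in WT, with a median of 1.12 and Ccnb2 (1.79 ± 0.13), Mad2l1 (1.74 ± 0.01), Ube2c (1.58 ± 0.08) and Nusap1 (1.49 ± 0.11) leading; Ccnb1 stood at 1.03 ± 0.21 without being called. In the DNA replication list 9 of 29 rose, Uhrf1 (1.84 ± 0.07), Tk1 and Tyms (both 1.69 ± 0.03) and Gmnn (1.58 ± 0.02) foremost, and the median was 0.84. Of 21 cholesterol genes 13 rose, with a median of 1.23, and of 36 chaperone genes 10 rose, with a median of 0.86 and Sdf2l1 (2.12 ± 0.20) and Pdia6 (1.63 ± 0.14) as examples. In the secretory epithelium list 7 of 22 rose and Cdh16 fell, with a median of 0.26; the members of the Sprr2 family are alike enough that their probes may not separate them. In the stromal and matrix list 6 collagen genes rose, Timp3 fell and 23 of 30 members did neither, with a median of 0.28, and smooth muscle markers had a median of 0.27 with no member called. Among epithelial markers 4 of 20 rose, Elf3, Cldn7 and Krt8 included, and the median was 0.22.

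Other lists moved the other way 24 h after E2 in WT. Genes of adipose tissue fell, namely Fabp4 (-2.51 ± 0.39), Adipoq (-2.22 ± 0.05), Cfd (-2.18 ± 0.24), Cidec (-1.95 ± 0.20) and Lpl, 5 of 21 on that list, on which Acta1 rose. The median of 6 adipose markers was -2.06 here, -1.17 in WT 2 h after estren and 0.12 in aERKO 24 h after E2. Macrophage and antigen presentation markers had a median of -0.30, with Cd74 called lower (-1.22 ± 0.09) and 25 of 26 not called. The median of T, B and NK cell markers was -0.12 with no member called. Mt2 (-1.995 ± 0.04), Ndrg1 (-1.96 ± 0.05) and Tsc22d3 (-1.39 ± 0.17) fell among targets of androgen, progesterone and glucocorticoid receptors. The early response list was back at 0.03, with Ramp3 (1.46 ± 0.01) called. The 448 calls became 834 with the scanner software's log ratio and 791 to 910 on either array alone; the share that was higher went from 58.3% to 74.7% with median centring of each array and was 44.1% without replicate 2.

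Estren at 2 h in WT uteri raised many of the genes that E2 raised. Inhbb rose by 4.40 ± 0.11, Gadd45g by 3.85 ± 0.06, the Polo-like kinase gene Plk2 by 3.40 ± 0.20, Errfi1 by 3.38 ± 0.08 and Ccn1, a matricellular protein gene, by 3.11 ± 0.14. Nr4a1, an orphan nuclear receptor gene, rose by 2.95 ± 0.01, followed by Greb1 (2.87 ± 0.07), Cebpb (2.84 ± 0.36), Ramp3 (2.84 ± 0.11), a modulator of the adrenomedullin receptor, and the nucleotide-sugar receptor gene P2ry14 (2.73 ± 0.12). Zfp503 (-2.34 ± 0.47), Apcdd1 (-2.19 ± 0.07), Ppp1r14c (-1.95 ± 0.60), Plekhs1 (-1.92 ± 0.15), Kcnj8 (-1.89 ± 0.02), Lratd1 (-1.67 ± 0.23), Rnf43 (-1.62 ± 0.18), a Wnt inhibitor gene, Scx (-1.61 ± 0.01), Fibin (-1.61 ± 0.10) and Txnip (-1.59 ± 0.19) fell most. Pgr rose by 1.20 ± 0.04, Igf1 by 1.24 ± 0.23, Cdkn1a by 1.62 ± 0.17, Myc by 1.22 ± 0.18 and Mad2l1 by 2.56 on each array, while Vegfa stood at 0.99 ± 0.01.

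Within the lists, 19 of 32 early response genes rose 2 h after estren in WT and none fell, with a median of 1.49. Chaperone genes had a median of 0.52, with 4 of 36 higher, Hsph1 at 1.74 ± 0.06 and Hspa5 at 1.33 ± 0.01 among them. Ribosome biogenesis genes had a median of 0.28, with 3 of 24 higher. Cholesterol genes had a median of 0.27, with 1 of 21 higher. Smooth muscle markers had a median of 0.29, with Oxtr called (1.19 ± 0.12). The replication and mitosis lists were centred on 0.03 and -0.04. In the adipose list 2 members fell, Cidec (-1.44 ± 0.26) and Adipoq (-1.24 ± 0.02). The total of 195 genes became 376 with the scanner software's log ratio and 309 to 456 on either array alone.

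At 24 h after estren in WT uteri 50 genes were higher and 40 lower. The acute-phase genes Saa3 (2.75 ± 0.09), Hp (2.70 ± 0.44) and Serpina3n (2.23 ± 0.15) and the kidney androgen-regulated protein gene Kap (2.59 ± 0.03) rose most, and Clca1 (2.16 ± 0.09), the troponin gene Tnni2 (1.99 ± 0.33), Spon1 (1.92 ± 0.19) and the cyclin gene Ccnb2 (1.91 ± 0.22) were also among the highest. Ltf, at -0.13 ± 0.04, was not called. In the mitosis list 7 of 30 rose and none fell, with a median of 0.91, and in the cholesterol list 5 of 21 rose, with a median of 0.41. Tk1 (1.11 ± 0.03) was the member called of 28 replication genes, whose median was 0.23. Col1a1 (1.49 ± 0.09), Col1a2 (1.42 ± 0.10) and Mmp3 (1.15 ± 0.08) rose among 30 stromal markers, whose median was 0.15. Smooth muscle markers had a median of 0.44 with none of 15 called.

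Among the genes that fell most 24 h after estren in WT were Ppp1r14c (-3.50 ± 0.34), Creb3l3 (-3.07 ± 0.84), Trim68 (-2.75 ± 0.67), Ptprz1 (-2.75 ± 1.15), Mrps17 (-2.72 ± 1.05), Adamts4 (-2.70 ± 1.47), Syt6 (-2.49 ± 1.10), Trim3 (-2.46 ± 0.60) and Duox2 (-2.43 ± 0.53). Most of these belong to the set of 12 genes with a high vehicle signal in the WT E2 and estren comparisons. Without genes of unlike WT vehicle signal, counted after seeing the data, 48 genes were higher and 21 lower, and with median centring 84 were higher and 33 lower. In the adipose list 6 of 21 members fell, Adipoq (-1.89 ± 0.01) and Fabp4 (-1.81 ± 0.26) among them. Macrophage markers had a median of -0.22, with Cd74 lower (-1.25 ± 0.17), and T, B and NK cell markers a median of -0.12. The 90 calls became 188 with the scanner software's log ratio and 172 to 280 on either array alone; the mean of the 2 arrays without the demand on each gave 164 genes, 77 higher and 87 lower.

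19NT at 24 h in WT uteri raised 39 genes and lowered 23. Clca1 (2.30 ± 0.10), Col1a1 (1.97 ± 0.23), Col1a2 (1.89 ± 0.10) and Tnni2 (1.88 ± 0.07) were among the highest. The adipose genes Fabp4 (-1.95 ± 0.13), Cfd (-1.91 ± 0.08) and Adipoq (-1.58 ± 0.03), with Galnt15 (-1.61 ± 0.03) and the carbonic anhydrase gene Car3 (-1.56 on each array), were lowest. Mitosis genes had a median of 0.68, with 5 of 30 higher, and cholesterol genes a median of 0.62, with 4 of 21 higher. In the stromal list 5 of 30 members rose, all matrix genes such as Sparc (1.53 ± 0.21) and Col3a1 (1.45 ± 0.04). Epithelial markers had a median of 0.38 without a called member. Ltf stood at 0.58 ± 0.13 and Igf1 at 0.27 ± 0.10, neither called. The 62 calls became 112 with the scanner software's log ratio.

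DHT at 24 h gave 17 higher and 4 lower genes. The troponin genes Tnnt2 (1.99 ± 0.02) and Tnni2 (1.49 ± 0.14), the mitotic kinase gene Pbk (1.46 ± 0.06) and the mitotic entry gene Cdca3 (1.32 ± 0.18) were among the highest. All the lower genes were the keratin gene Krt15 (-1.53 ± 0.23), Pamr1 (-1.12 on each array), Chchd10 (-1.10 ± 0.09) and Ggt5 (-1.09 ± 0.02). Mki67, Ccnb2 and Aurkb rose among 30 mitosis genes, whose median was 0.64, and Tk1 (1.22 ± 0.18) among 29 replication genes, whose median was 0.43. In the cholesterol list 3 of 21 rose, Fdps and Idi1 included, and the median was 0.29. Ltf stood at -0.70 ± 0.01 and Greb1 at -0.27, neither called. The 6 adipose markers followed across comparisons had a median of -0.09. The 21 calls became 68 with the scanner software's log ratio and 40 to 43 on either array alone.

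**Figure D2:**
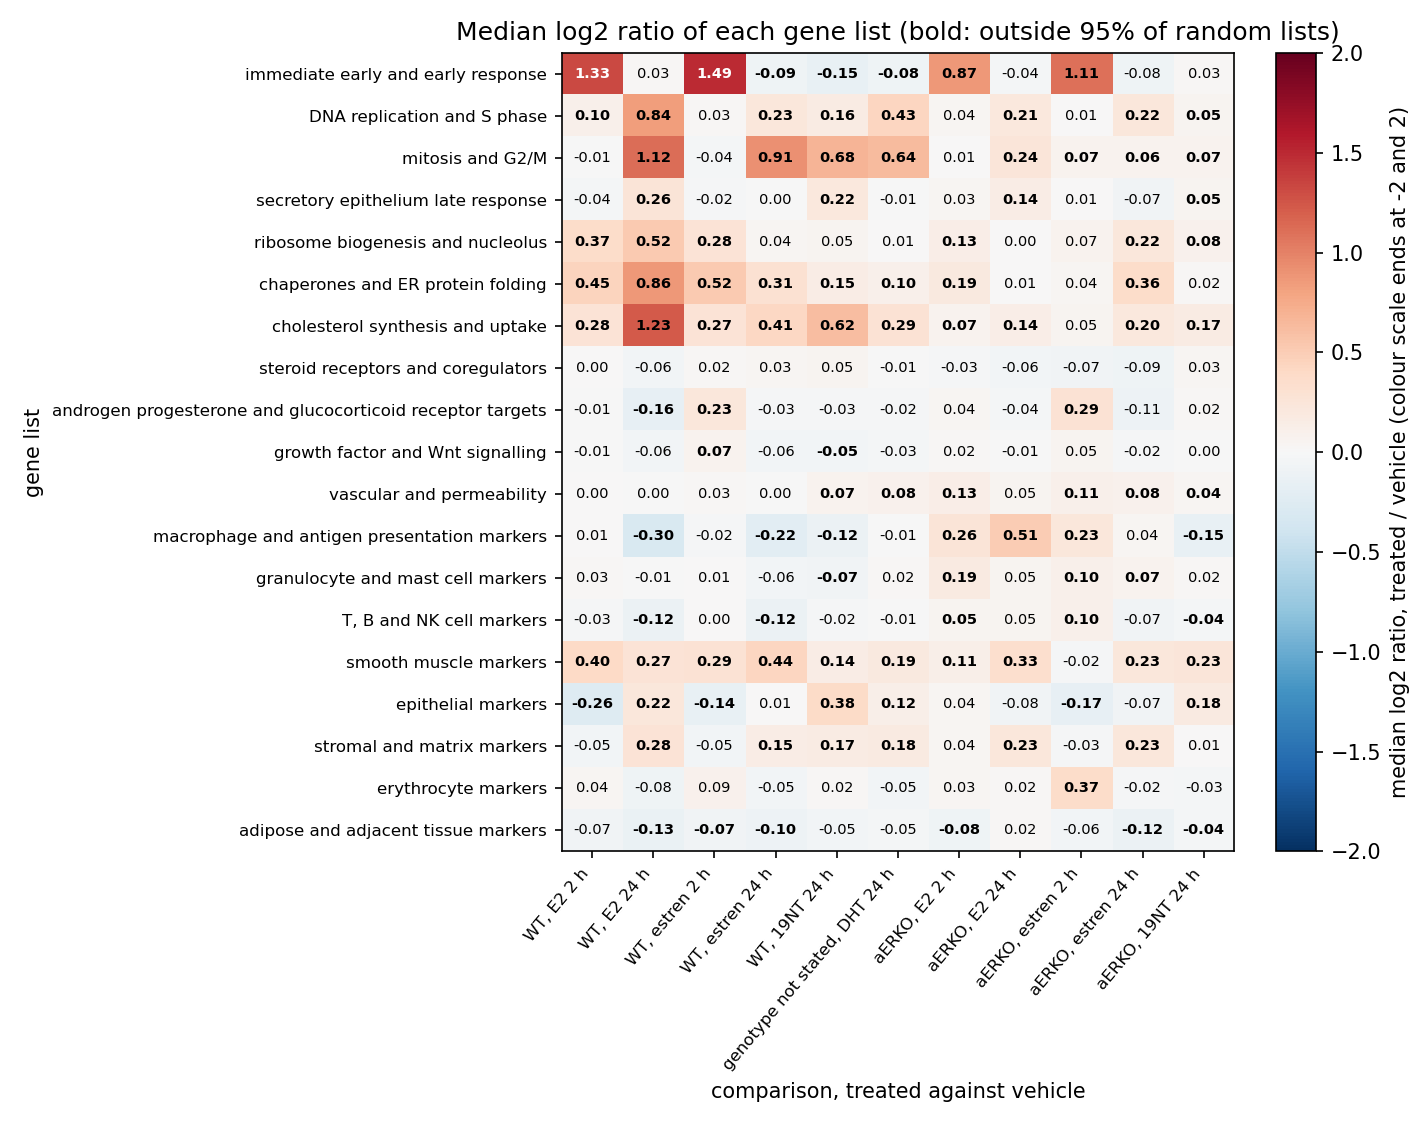
Median log2 ratio, treated over vehicle, of each of the 19 gene lists (vertical axis) in each of the 11 comparisons (horizontal axis), with red for higher, blue for lower and bold print where the median lay outside the central 95% of random lists. The mitosis list stands at 1.12, 0.91, 0.68 and 0.64 in the E2, estren and 19NT comparisons in WT and in the DHT comparison at 24 h, and at 0.24, 0.06 and 0.07 in aERKO.

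Estren and E2 were set side by side in WT uteri at matched times, though at different doses and without a test. At 2 h all 324 genes called under E2 and measured under both moved in the same direction under estren, and 193 of them passed 2-fold there on the mean of the 2 arrays. Their median size was 1.502 under E2 and 1.15 under estren. Across genes, which are not independent replicates, the ratios had a correlation of 0.866 and a covariance of 0.101. Simulated unchanged pools against a shared vehicle, with their spread taken from the aERKO comparisons, gave a covariance of 0.00908. Both compounds raised 129 genes, against 2.25 from independent lists, and lowered 27, against 0.143. Whether the comparisons shared a vehicle pool is not stated, so part of this excess may come from shared controls. The vehicle signals of E2 and estren in WT differed at least 2-fold in 5 genes at 2 h and in 26 at 24 h. Against the WT 19NT vehicle, that of E2 differed in 457 genes at 2 h and in 552 at 24 h. The E2 and estren arrays also shared 1 extraction day, so a shared pool and a shared day cannot be told apart. Klk1b5 rose less under estren by -1.78, with a 95% interval over array error of -2.22 to -1.35, as did Slc9a2 (-1.50), Trim15 (-1.45), Pqlc3 (-1.41) and Ube2e1 (-1.37). Dio2, the deiodinase that makes active thyroid hormone, was higher under estren by 1.51 with an interval of 1.19 to 1.84, and Hoxa10 (1.29), Nr2f2 (1.19), Plk2 (1.03) and Txnip (1.00) also stood higher. For Greb1 the interval of the difference was -0.61 to 0.19. E2 lowered Hoxa10, Nr2f2 and Txnip, so for these a higher value under estren is a weaker fall. The signed ratio under estren lay below that under E2 beyond array error in 154 of 343 genes called under either, and above it in 53. These counts do not separate larger from smaller responses, and most of the genes were called under E2.

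At 24 h the responses to estren and E2 in WT were further apart. Of 447 genes called under E2, 435 moved in the same direction under estren and 94 passed 2-fold there on the mean of the 2 arrays. The median size was 1.37 under E2 and 0.67 under estren. The correlation across genes was 0.813, and the covariance of 0.0937 compared with 0.0105 in the simulation. Shared calls numbered 32 higher, against 0.717 from independent lists, and 36 lower, against 0.421. The 36 include all 12 genes with the high vehicle signal; without genes of unlike WT vehicle signal, counted after seeing the data, 21 were lower under estren, so at most 21 of the 36 remain. Sprr2f differed by -3.35 (interval -3.56 to -3.14), with Padi2 (-2.74), Alpl (-2.23), Prxl2a (-2.22), Dio2 (-1.97) and Ltf (-1.91, interval -2.13 to -1.68) also lower under estren. Saa3 was higher under estren by 3.09 (interval 2.77 to 3.42), as were Inmt (2.73), Tgfbi (2.35), Kap (2.31) and Serpina3n (2.16); E2 lowered Inmt and Tgfbi, and Saa3, Kap and Serpina3n were not called under E2.

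**Figure D3:**
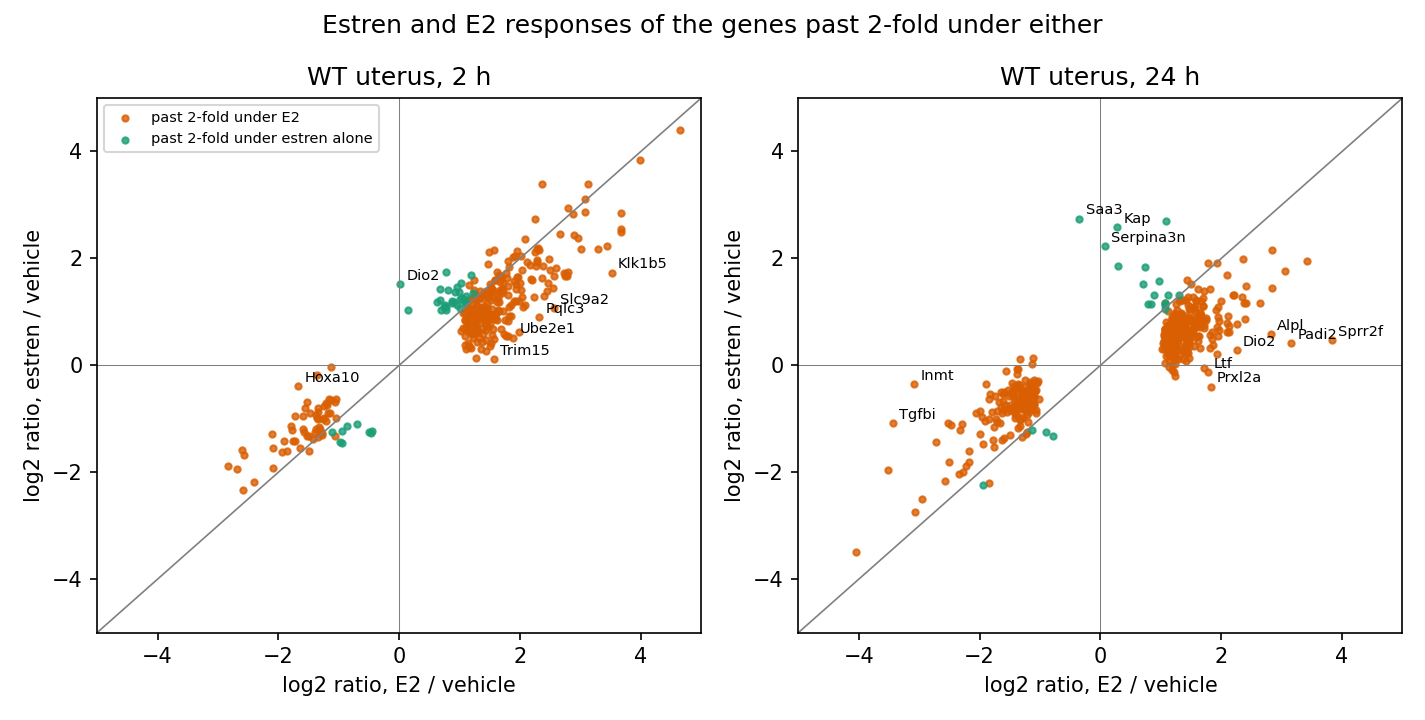
Log2 ratio against vehicle under estren (vertical axis) and under E2 (horizontal axis) in WT uteri at 2 h and 24 h, for the genes past 2-fold under E2 (orange) or under estren alone (green), with a grey line where the ratios are equal. The median size of the E2-called genes was 1.15 under estren and 1.502 under E2 at 2 h, and 0.67 and 1.37 at 24 h.

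19NT in WT moved 417 of 443 E2-called genes in the E2 direction at 24 h, with a median of 0.52 against 1.37, and 54 passed 2-fold on the mean of the 2 arrays. The correlation was 0.683 and the covariance 0.0629, against 0.0103 simulated. Shared calls were 33 higher, against 0.558 from independent lists, and 14 lower, against 0.238. Sprr2f (-3.04), Padi2 (-2.88), Dio2 (-2.67), Alpl (-2.63) and Prxl2a (-1.94) were lower under 19NT than under E2, and Ppp1r14c (4.03), Ptprz1 (3.10), Syt6 (2.98), Tgfbi (2.55) and Itgb8 (2.42) were higher. Ppp1r14c and Ptprz1 are among the 12 genes whose median vehicle signal was 11.14 in the WT E2 and estren comparisons and 8.13 in the WT 19NT comparison. Against estren, 75 of 90 estren-called genes moved in the same direction under 19NT, with medians of 0.90 and 1.40. The 50 higher genes had medians of 1.01 under 19NT and 1.32 under estren, and the 40 lower ones -0.50 and -1.71. Those 12 genes are among the 40, had a median of 0.02 under 19NT, and 7 of them stood above 0 there. The comparison had a correlation of 0.669 and a covariance of 0.0394 against 0.0105 simulated. Here 22 higher and 12 lower genes were shared, against 0.110 and 0.0517. Hp (-2.98), Kap (-2.76), Serpina3n (-2.44), Saa3 (-2.28) and Spp1 (-2.01) were lower under 19NT than under estren, and Ppp1r14c (3.48), Ptprz1 (2.77), Prap1 (2.73), Syt6 (2.53) and Brf2 (2.08) were higher, where Ppp1r14c, Ptprz1 and Brf2 are of those 12 genes. On genes chosen from a single estren array the 19NT median was 0.37 or 0.70, beside 0.59 or 1.06 for estren on its other array.

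DHT moved 404 of 447 E2-called genes in the E2 direction, with a median of 0.38 against 1.37 and 19 past 2-fold on the mean of the 2 arrays. The correlation was 0.568 and the covariance 0.0458, against 0.0105 simulated. They shared 13 higher genes, against 0.249 from independent lists, and 1 lower gene, against 0.0417. Sprr2f (-3.56), Padi2 (-3.22), Alpl (-2.75), Lcn2 (-2.73) and Clca1 (-2.53) were lower under DHT, and Ppp1r14c (3.18), Tgfbi (2.89), Inmt (2.74), Galnt15 (2.63) and Ptprz1 (2.42) were higher. The 12 genes that include Ppp1r14c and Ptprz1 had a median vehicle signal of 8.99 in the DHT comparison. The compound and the unstated genotype cannot be told apart in this comparison.

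In aERKO uteri 36 genes were higher and 1 lower 2 h after E2. Nr4a1 (3.06 ± 0.20), Gadd45g (2.55 ± 0.05), Ccn1 (2.499 ± 0.10), the transcription factor gene Egr1 (2.48 ± 0.01) and the neutrophil calprotectin gene S100a9 (2.47 ± 0.03) rose most, and Npl (-1.17 ± 0.16), a sialic acid lyase gene, fell. Of 32 early response genes 10 rose and none fell, with a median of 0.87. Ltf (2.08 ± 0.09) and Myc (1.49 ± 0.08) rose, whereas Inhbb stood at 0.97 ± 0.02, Greb1 at 0.83 ± 0.06 with its vehicle signal well above background on 1 array, and Mad2l1 at 0.50 ± 0.07. Macrophage markers had a median of 0.26 and granulocyte markers one of 0.19, with Ccl2, S100a9 and S100a8 called. The haemoglobin genes Hbb-b2 (1.59 ± 0.11) and Hba-a1 (1.40 ± 0.09) rose too, 2 of 7 erythrocyte markers. The WT and aERKO responses shared 17 higher genes, against 0.506 from independent lists, and the genes called in WT had a median of 0.27 in aERKO against 1.49. The 37 calls became 81 with the scanner software's log ratio, 19 without background subtraction and 66 without replicate 1.

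At 24 h after E2 in aERKO 22 genes were higher and 1 lower. The complement genes Cfb (1.84 ± 0.01) and Cfi (1.47 ± 0.02), Lcn2 (1.77 on each array), Ltf (1.62 ± 0.04) and the chemokine gene Ccl8 (1.60 ± 0.08) rose most, and Tgfbi (-1.13 ± 0.06) fell. Lcn2, Ltf, Clca1 (1.19 ± 0.04) and Sprr2f (1.12 ± 0.01) made up the 4 of 22 secretory epithelium genes that rose. Macrophage markers had a median of 0.51, with Ccl8 called, and mitosis genes a median of 0.24 with none of 28 called. DNA replication genes had a median of 0.21, also with none of 28 called. With WT, 7 higher genes were shared, Clca1, Tnni2, Cfb, Ltf, Sprr2f, Lcn2 and Muc4, against 0.320 from independent lists, and Tgfbi fell in both. The genes called in WT had a median of 0.26 in aERKO against 1.36. The 23 calls became 69 with the scanner software's log ratio, 5 without background subtraction and 41 to 48 on either array alone.

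Estren at 2 h in aERKO uteri raised 54 genes and lowered 5. Nr4a1 (3.13 ± 0.01), Gadd45g (2.59 ± 0.18), Errfi1 (2.57 ± 0.01), the AP-1 gene Junb (2.53 ± 0.20) and the cytokine signalling inhibitor gene Socs3 (2.48 ± 0.19) were highest; Prr15 (-1.62 ± 0.11), Grb7 (-1.48 ± 0.09), Rhpn2 (-1.33 ± 0.02), the fatty acid synthase gene Fasn (-1.07 ± 0.02) and Mmp12 (-1.01 on each array) fell. Of 32 early response genes 16 rose and none fell, with a median of 1.11. Sgk1 (2.04 ± 0.28) and the metallothionein gene Mt1 (1.24 ± 0.12) rose among 18 targets of androgen, progesterone and glucocorticoid receptors, whose median was 0.29. In WT 2 h after estren the median of that list was 0.23, which also stood apart. At 2 h after E2 it was -0.01 in WT and 0.04 in aERKO, within random lists. Sgk1 was called higher in each of these. The chemokine genes Ccl2 (2.15 ± 0.38), Ccl8 (1.20 ± 0.18) and Ccl7 (1.18 ± 0.18) rose among 26 macrophage markers, and Hbb-b2 (1.16 ± 0.09) among 7 erythrocyte markers, whose median was 0.37. With WT, 28 higher genes were shared, against 0.481 from independent lists, and Grb7, Prr15 and Rhpn2 fell in both; the WT-called genes had a median of 0.42 in aERKO against 1.42. The 59 calls became 101 with the scanner software's log ratio, 23 without background subtraction and 90 to 97 on either array alone.

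At 24 h after estren 47 genes were higher and 32 lower in aERKO. Saa3 (3.49 ± 0.10), Hp (3.41 ± 0.26), S100a9 (3.32 on each array), Serpina3n (3.02 ± 0.18) and S100a8 (2.45 ± 0.11) rose most, and Galnt15 (-2.26 ± 0.01), Car3 (-2.18 ± 0.09), Coch (-1.84 ± 0.29), Retnla (-1.78 ± 0.19) and Inmt (-1.77 ± 0.22) fell most. Saa3, Hp, Serpina3n, S100a9, Spp1, Cfb and Cxcl10 were among 14 genes higher in both genotypes, against 0.120 from independent lists, and 11 were lower in both, against 0.0742. The WT-called genes had a median of 0.87 in aERKO against 1.42. Adipoq (-1.28 ± 0.05), Lpl (-1.24 ± 0.19) and Cidec (-1.15 ± 0.14) fell among 21 adipose list members. Cxcl5 (1.31 ± 0.14) was called with S100a9 and S100a8 among 20 granulocyte and mast cell markers, whose median was 0.07, and Ccl2 (2.09 ± 0.18), Ccl8 (1.73 ± 0.005) and Ccl7 (1.43 ± 0.03) among 26 macrophage markers, whose median was 0.04. Mitosis genes had a median of 0.06 with none of 25 called. DNA replication genes had a median of 0.22 with none of 27 called, beside 0.23 in WT. The chaperone list had one of 0.36 with 1 of 34 called, Sdf2l1, beside 0.31 in WT. Both aERKO medians stood apart from random lists. The 79 calls became 142 with the scanner software's log ratio, 32 without background subtraction and 175 to 202 on either array alone, where 86 higher and 89 lower or 95 higher and 107 lower genes were counted; with median centring 70 were higher and 17 lower.

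19NT at 24 h in aERKO gave 10 higher genes and 1 lower. Acod1 (2.07 ± 0.10), which makes itaconate in activated macrophages, S100a9 (1.95 ± 0.09), Lcn2 (1.77 ± 0.15), the neutrophil chemokine gene Cxcl5 (1.68 ± 0.08) and S100a8 (1.41 ± 0.07) were highest, and the lower gene had no symbol. Sprr2f (1.37 ± 0.11) rose as well. Macrophage markers had a median of -0.15 with none of 26 called, and smooth muscle markers one of 0.23. Tspan1 was the gene higher in both genotypes, against 0.0210 from independent lists. Across genes the 2 arrays had a correlation of 0.0610, so most of the spread of the ratios here was array error. In aERKO this correlation was 0.318 at 2 h and 0.209 at 24 h after estren, and 0.362 and 0.551 after E2. It was 0.401 to 0.782 in the WT comparisons. Array error was thus a large part of the spread under estren in aERKO as well.

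**Figure D4:**
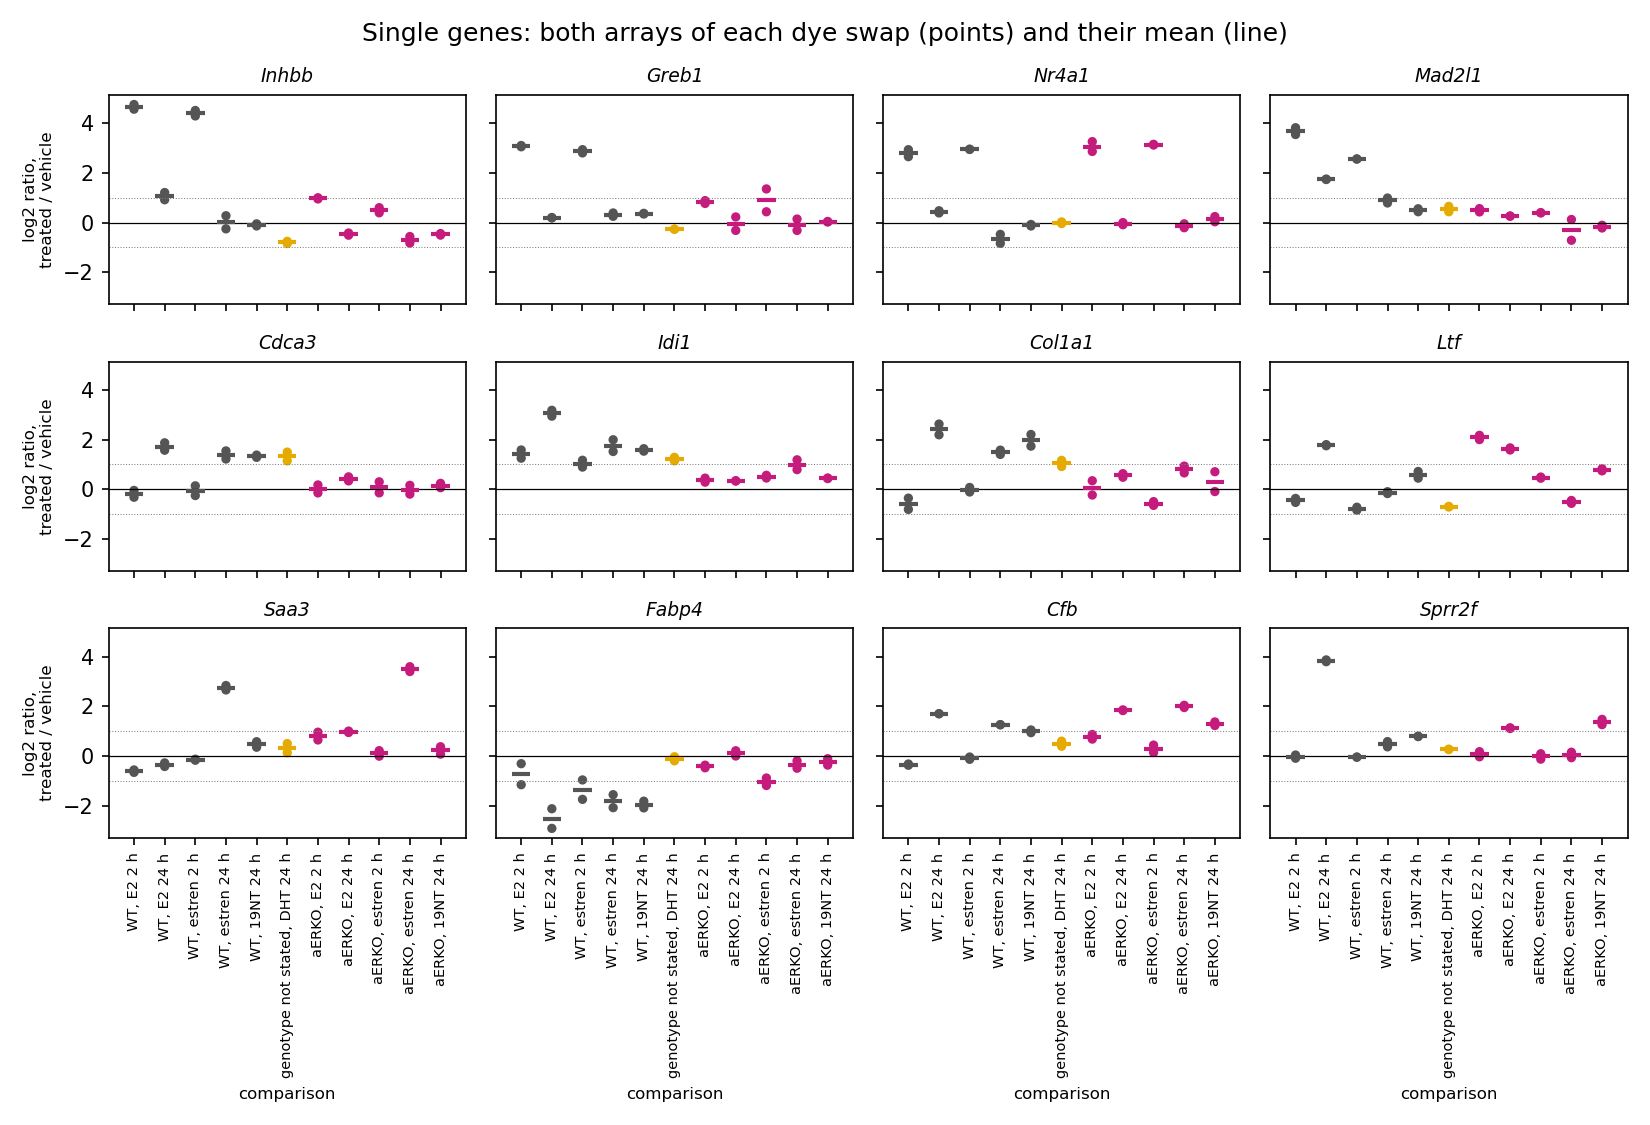
Log2 ratio against vehicle of 12 single genes (vertical axis) in the 11 comparisons (horizontal axis), with a point for each array, a line for their mean and dotted lines at 2-fold; WT is grey, aERKO magenta and the DHT comparison yellow. Inhbb stood at 4.65 and 4.40 in WT 2 h after E2 and estren and at 0.97 and 0.50 in aERKO, whereas Nr4a1 passed 2-fold at 2 h in both genotypes.

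The genotype difference was tested across compounds, with each dye-swap mean as 1 replicate, in limma. The error in this test is how the difference varied between compounds, not between mice. It is pooled over both times, so the test at 2 h also rests on the spread between compounds at 24 h, 19NT included. Whether the compounds shared a vehicle pool within a genotype is not stated. If they did, the compounds are not independent replicates at either time, and an odd vehicle pool could pass as a genotype difference. Between E2 and estren at 2 h the vehicle signals differed at least 2-fold in 5 genes in WT and in 46 in aERKO. These counts leave open whether pools were shared. At 2 h, over E2 and estren, 110 of 18388 genes passed an adjusted p of 0.05, 88 with a higher response in WT and 22 with a lower one, each in the same direction under both compounds, and 2834 passed an unadjusted p of 0.05. Inhbb differed by 3.79 (SE 0.27, adjusted p = 0.0275), Mad2l1 by 2.67 (SE 0.29, adjusted p = 0.0445), Ramp3 by 2.63 (SE 0.21, adjusted p = 0.0275) and Greb1 by 2.11 (SE 0.09, adjusted p = 0.0121). P2ry14, the aquaporin gene Aqp5, Dennd2a, the transcription factor gene Stat5a, the amino acid transporter gene Slc7a5 and the creatine kinase gene Ckb completed the largest differences, between 2.16 and 1.88. Vegfa differed by 0.92 (adjusted p = 0.0437), while Cdkn1a (1.29, adjusted p = 0.0707), Pgr (0.77, adjusted p = 0.122) and Ltf (-1.89, adjusted p = 0.0807) did not pass. Lower in WT were Tnfaip8 (-1.40), the pattern-recognition receptor gene Nod1 (-1.24), the interferon-inducible gene Ifi205 (-1.19), the cytokine gene Il15 (-1.16), the BMP pseudoreceptor gene Bambi (-0.998), Flrt3 (-0.97), Rab15 and Slc37a4 (both -0.85), Gbp4 (-0.84) and a transcript without a symbol. Leaving E2 or estren out of the fit left a single value per genotype at 2 h. The error in these fits came from 24 h alone, so they cannot judge the difference at 2 h. Without 19NT, which left fewer residual degrees of freedom, 0 genes passed in limma at 2 h, with 2609 at an unadjusted p under 0.05. The scanner software's log ratio gave 32 genes and no background subtraction gave 275. Without subtraction the calls at 2 h under E2 and estren fell from 37 to 19 and from 59 to 23 in aERKO. In WT they fell from 325 to 292 and from 195 to 171. The 275 may thus come from smaller aERKO ratios and add no weight to the difference.

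Among the lists at 2 h, the early response genes had a median genotype difference of 0.20. Of 32 members 2 passed over all genes, Hbegf and Ramp3, and 11 when adjusted over the list alone, all higher in WT; fry, which tests whether the members moved one way on balance, gave an adjusted p of 0.134. Camera, which compares a list with the other genes, gave an adjusted p of 0.000263 with its preset correlation and an adjusted p of 0.443 with an estimated correlation. In the smooth muscle list Cnn1 and Oxtr passed over all genes and 3 of 17 when adjusted over the list alone, with a median of 0.27; fry gave an adjusted p of 0.0523, and camera 2.49e-05 preset and an adjusted p of 0.420 with an estimated correlation. No list at either time kept its camera call with an estimated correlation. At 2 h the mitosis list had a median of -0.04 and a mean of 0.04. WT and aERKO arrays for E2 and estren were extracted on different days, so at 2 h genotype and day cannot be told apart.

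At 24 h, over E2, estren and 19NT, 4 genes passed, all with a higher response in WT under each of the 3 compounds, and 2280 passed an unadjusted p of 0.05. They were Cdca3 (1.29, SE 0.06, adjusted p = 0.0210), the centromere histone gene Cenpa (1.22, SE 0.06, adjusted p = 0.0247), the anaphase-promoting complex partner Ube2c (1.13, SE 0.07, adjusted p = 0.0387) and the spindle gene Knstrn (1.12, SE 0.05, adjusted p = 0.0210). Under 19NT, whose arrays for both genotypes were extracted on 1 day, the differences were 1.18, 1.21, 1.00 and 1.11 for Cdca3, Cenpa, Ube2c and Knstrn, but these values were part of the fit that picked the genes and are no separate check of them. Mitosis genes had a median difference of 0.80; 2 of 29 passed over all genes and 28 when adjusted over the list alone. Fry gave this list an adjusted p of 0.0131, and camera 1.94e-35 preset and an adjusted p of 0.300 with an estimated correlation. The cholesterol list had a median of 0.53, with none of 21 past over all genes in limma and 17 when adjusted over the list alone; fry gave an adjusted p of 0.215, and camera 2.40e-13 preset and an adjusted p of 0.458 with an estimated correlation. The count of 4 fell to 0 in limma without E2, estren or 19NT, with 1416, 1880 and 1935 genes at an unadjusted p under 0.05. It was 0 with the scanner software's log ratio, with 2055 genes at an unadjusted p under 0.05. Without background subtraction it was 28, a setting that cut the aERKO calls under E2 and estren from 23 to 5 and from 79 to 32.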

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

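The test over other splits of the samples was planned; the tests of vehicle levels, of probes reading a common RNA, of a share of WT RNA and of adipose tissue were chosen only after the result was seen.

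The response to the compounds differed between genotypes in 4 genes at 24 h and in 110 genes at 2 h, by a limma test of the difference itself. Of the 10 splits of the 6 values at 24 h, 3, the real one included, gave at least as many genes as the real 4, and the highest other split gave 459. With 10 splits no share under 0.05 can be had. The splits with 459 genes put both genotypes of estren on one side and both of 19NT on the other, or the reverse, with only the genotypes of E2 parted. With condition as a block, these counts rest on the genotype contrast under E2 alone, a structure of the samples, and say nothing of chance. Under 19NT alone, with both genotypes extracted on 1 day, 44 genes differed by at least 2-fold with the arrays of the genotypes apart, a count chosen after seeing the data and without a test.

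A probe for an immunoglobulin lambda variable region without a symbol stood at -1.128 in WT and at 1.251 in aERKO 24 h after E2, and at 1.442 in WT 2 h after E2. It drew attention because both arrays of each comparison moved opposite ways between genotypes and between times. The difference was not tested.

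Of the 14 genes lower in WT under E2 at 2 h, E2 at 24 h and estren at 24 h, 12 had a vehicle level at least 2-fold above that of the WT 19NT comparison, 85.7% against 0.688% of all genes. Galnt15 and Cd83 were the 2 without it. The 12 had a median level of 11.14 in the vehicle RNA of the WT E2 and estren comparisons and 8.13 in the WT 19NT vehicle. It was 8.08 in WT RNA treated with E2 for 24 h, so their fall may come from the vehicle pools. Other vehicle medians were 9.85 in aERKO with E2 and estren, 8.30 in aERKO with 19NT and 8.99 with DHT. In WT each of the 12 fell less at 2 h than at 24 h under both E2 and estren. A call was required under estren at 24 h but not at 2 h, so the choice favours this order under estren. The vehicle level above is a mean over both times, and the 12 moved closely together. The order in time therefore cannot decide whether a high vehicle level alone accounts for the fall. That the probes read 1 common RNA cannot be told apart from a high level of 12 separate RNAs. The median correlation between pairs of the genes was 0.976, and the probe sequences were not used here. A change made by the compounds stays open as well, untested.

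Of 32 early response genes, 10 rose 2 h after E2 and 16 after estren in aERKO, Nr4a1, Gadd45g and Egr1 among them. A share of WT tissue or RNA in the aERKO pools is argued against only as the sole source of this rise. The share was set by the median response of the list itself, 32.6% of WT under E2 and 52.2% under estren. Of 234 other genes higher in WT under E2, 211 lay below the ratio that such a share would give, as did 117 of 138 under estren. In all these were 328 of 372 values, with genes higher under both compounds counted under each. A smaller share beside another cause was not tested. Greb1 in aERKO reached 10.4% of its WT rise under E2 and 13.6% under estren. Nr4a1 in aERKO reached 116% of its WT rise under estren and Inhbb 2.05%. Whether the vehicle pools were taken 2 h after injection cannot be told apart from a response to the compound, because the labels give no vehicle time; the vehicle level of the list differed between 2 h and 24 h by 0.0266 with estren and 0.10 with E2. A response of these genes to the injection or to the compounds without estrogen receptor alpha may therefore underlie the rise, and neither was tested.

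The 6 adipose markers had medians of -2.06 and -1.55 in WT 24 h after E2 and estren, and of -0.89 in aERKO 24 h after estren. The median under 19NT in WT, where the vehicle arrays belonged to another day, was -1.42. This cannot decide whether the WT E2 and estren vehicle pools were rich in adipose tissue. The 19NT vehicle may have been rich as well. In WT the median vehicle level of the 6 was 10.77 with 19NT and 11.075 to 11.135 with E2 and estren. With DHT it was 10.36, and in aERKO with E2 and estren it was 12.51 to 12.70. The 6 are the list members called lower in WT 24 h after estren, so their fall there was set by the choice. Their span of 0.676 in that comparison is therefore no separate check. All 6 stood below 0 with a median of -1.17 already 2 h after estren in WT. The whole adipose and adjacent tissue list had medians of -0.07 at 2 h and -0.10 at 24 h there. Less adipose tissue in the treated pools may account for the fall of the 6, but genes picked this way cannot decide it. A fall of these transcripts within adipose cells was not tested.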

How the results depend on the processing

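The tests without genes of unlike WT vehicle level and of 19NT alone were chosen only after the result was seen; the others were planned. Counts are in the order WT E2 2 h, E2 24 h, estren 2 h, estren 24 h and 19NT, DHT, then aERKO E2 2 h, E2 24 h, estren 2 h and estren 24 h, beside 325, 448, 195, 90, 62, 21, 37, 23, 59 and 79. The deposited log ratio gave 548, 834, 376, 188, 112, 68, 81, 69, 101 and 142, and the deposited table of values gave 545, 834, 373, 187, 111, 68, 80, 69, 100 and 140. The deposited p under 0.001 on both arrays gave 1010, 1776, 799, 514, 338, 168, 146, 215, 144 and 339, and 39 in place of 11 for 19NT in aERKO. Without replicate 1 or 2 the ranges were 505 to 702, 791 to 910, 309 to 456, 172 to 280 in WT, 40 to 43 for DHT, and 45 to 66, 41 to 48, 90 to 97 and 175 to 202 in aERKO. The mean of the 2 arrays alone gave 719 for WT E2 24 h, 164 for WT estren 24 h and 41 for aERKO E2 24 h. Without background subtraction the 4 aERKO counts of E2 and estren were 19, 5, 23 and 32. These aERKO arrays had green backgrounds of 267 to 278 against 43 to 47 in the WT arrays for the same compounds, so the signal over background limits what dim probes can show there. The causes of these moves were not tested.

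The genotype difference gave, at 24 h beside 4 and at 2 h beside 110, 0 and 32 genes with the deposited log ratio, 28 and 275 without background subtraction, 66 and 479 without the block, and 73 at 2 h with median centring. The larger counts without background subtraction may come from smaller aERKO ratios, since aERKO calls fell more than WT calls in that setting. Array 1 alone gave 0 and 56 and array 2 alone 0 and 68. The counts of 0 are from limma, where 2055, 2230 and 1423 genes had an unadjusted p under 0.05 with the log ratio, array 1 and array 2. Leaving out each compound in turn gave 0 at 24 h in limma, with fewer values in the fit and 1416 to 1935 genes at an unadjusted p under 0.05. At 2 h, leaving out 19NT gave 0 in limma, with 2609 genes at an unadjusted p under 0.05. Without E2 or estren a single value per genotype was left at 2 h, and the error came from 24 h alone, so these fits cannot judge 2 h. 19NT alone gave 44.

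The median under the second compound of genes called under the first went from 1.15 to 0.91 and 0.83 for estren against E2 at 2 h with genes chosen on array 1 or array 2, where E2 on its other array gave 1.22 and 0.94. At 24 h it went from 0.67 to 0.72 with the deposited log ratio, 0.71 with median centring and 0.54 and 0.58 with genes chosen on 1 array, where E2 gave 1.10 and 0.99. For 19NT against E2 it went from 0.52 to 0.49, and to 0.43 and 0.37 beside 1.10 and 0.99 for E2. For 19NT against estren it went from 0.90 to 0.79, to 0.96 with median centring, and to 0.37 and 0.70 beside 0.59 and 1.06 for estren. For DHT against E2 it went from 0.38 to 0.34 with median centring, and to 0.32 and 0.27 beside 1.10 and 0.99 for E2.

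Of the list medians that stood apart, 103, 106, 101 and 105 of 108 did so with the deposited log ratio, the mean over probes, median centring and no filter, and none changed sign in these. None of 441 called values of named genes changed sign with the deposited log ratio, no background subtraction or median centring, and 441, 406 and 429 of them stayed at least 2-fold in size. Without genes of unlike vehicle level the WT counts of E2 and estren were 302, 417, 186 and 69.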

Other observations

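The genes and the list in these paragraphs were picked only after the result was seen. The limma, fry and camera tests were planned.

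Saa3, Hp and Serpina3n were higher 24 h after estren in both genotypes. Saa3 stood at 2.75 in WT and 3.49 in aERKO, Hp at 2.70 and 3.41, and Serpina3n at 2.23 and 3.02, all called. In WT 24 h after E2, Saa3 (-0.35), Serpina3n (0.07) and Hp (1.09, with 0.57 and 1.60 on the 2 arrays) were not called, so Hp alone of the 3 stood past 2-fold on the mean. The granulocyte marker S100a9 was called in both genotypes as well 24 h after estren, at 1.59 in WT and 3.32 in aERKO, while S100a8, Cxcl5, Ccl2, Ccl7 and Ccl8 were called in aERKO and not in WT. The difference between compounds was not tested across mice, nor that between genotypes under estren alone; over 3 compounds at 24 h none of these 9 genes passed the threshold for a genotype difference in limma, with adjusted p values of 0.173 to 0.985.

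Macrophage markers had opposite medians 24 h after E2 in the genotypes, -0.30 in WT and 0.51 in aERKO. The median genotype difference of that list over 3 compounds was -0.32, with no member past the threshold in limma. Fry gave an adjusted p of 0.269. Camera gave an adjusted p of 1.56e-07 with its preset correlation and an adjusted p of 0.458 with an estimated correlation.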
